A study of Caenorhabditis elegans with 2 samples.

How the data were processed

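ChIP-seq peak lists of LIR-3 tagged with GFP were analysed for 2 biological replicates of whole L1 larvae, 6 h after synchronization. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP. Per the file descriptions deposited with the samples, the authors called peaks and background regions for each replicate and for both replicates pooled, each with a further input file that is not among the samples, and derived the IDR set from these 3 lists. Each list before the threshold holds 30000 regions. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. Per the labels, a control experiment exists, and it was not analysed here.

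Each deposited list gives, for every peak, its position, its summit, a score and a −log10 q-value. The score is the authors' signal value for the peak, with no unit given in the deposited files. The −log10 q-values in the deposited files are the authors' too, and reach their highest value, 2.01, for 1458 of the 1894 nuclear IDR peaks, so that peaks were ranked by score. All 1910 IDR peaks are present with the same position and score in the pooled list, so that the score of an IDR peak is that of the pooled data. The lists are deposited on ce11 and ce10. The ce11 lists were used with the matching reference annotation (Ensembl release 115, names of tRNA and mitochondrial genes from RefSeq), and the ce10 lists only for counts within that build. No column of the files was left unmatched to a sample or the pooled group. Read depth is unknown, so no depth per sample is given, and the precision of a share is given as an exact Clopper-Pearson 95% interval over genes or peaks, which covers counting error only. Genes and peaks are not replicates, and neighbouring genes can share a summit, so the p-values cover counting or placement and not the spread between worms.

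The main results use nuclear peaks of the IDR set. A gene was counted as having a peak when an IDR summit lay within 500 bp of its annotated 5' end. Genes of 10 biotypes (background 46890 nuclear genes) and 29 lists of protein-coding genes (background 19973) were compared with the remaining genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over biotypes and over lists. The share of summits near 5' ends was compared with 1000 random placements on the same chromosomes, and peak scores by class with 100000 permutations over 15 classes of at least 10 peaks. For 8 sequence motifs, windows of 100 bp on each side of summits were compared with windows centred 500 bp away that held no IDR summit. The lists, motifs, tests and alternatives were fixed before the data were examined, apart from those named as chosen later. Some list symbols have no gene of that name in the annotation and were left out.

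Genes are named by a rule fixed in advance: lir-3, unc-119, lin-26, lir-1 and lir-2; the gene with the 5' end nearest to each of the 20 strongest IDR peaks, within 500 bp; and up to 4 members with the strongest peaks of each biotype or list that passed. Because 13 of those 20 peaks are mitochondrial, genes at further nuclear peaks were added after the values were seen.

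The alternatives were windows of 250 and 1000 bp, any base of the peak in the window, the 947 strongest IDR peaks, and assignment of each summit to the nearest gene, which leaves piRNA genes out. Further ones were a background of genes near a pooled pre-threshold summit, a background without piRNA genes (chosen after seeing the data), leaving out summits near small RNA genes, other flanks, reciprocal overlap of at least 50%, the 500 strongest peaks, the ce10 lists, and leaving out each replicate. For the last, the 1894 strongest peaks of the remaining replicate's list were used (for peak strength, its scores). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. The class test was tested on simulated data, with summits drawn at 5-fold weight for 4 classes in 20 runs. It called the ribosomal protein list (81 genes) in 20 runs, collagens (177) in 20, the proteasome (33) in 16 and tRNA genes (612) in 20, and it called 2.12% of the unchanged lists. All simulated summits were placed near gene 5' ends, against 67.4% in the data, with a single summit per drawn gene. No list was drawn at lower weight, and no changed list was smaller than 33 genes, so detection in those cases is not known.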

Results

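LIR-3 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hermaphrodite L1 larvae of Caenorhabditis elegans, collected 6 h after synchronization. The larvae carried a transgene in which lir-3, a gene of the lin-26 family, is fused at its C-terminus to GFP and FLAG, and DNA was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates and no control group among the samples, so no test between groups was possible. The question the design addresses is where in the genome the tagged protein is found. The authors' IDR set, labelled optimal, holds the peaks that passed their threshold on the irreproducible discovery rate. It held 1910 peaks, of which 1894 were on the nuclear chromosomes and 16 on the mitochondrial genome. Read depth is unknown, because the files give peaks and no read counts. Peak scores are the authors' own and are used only to rank peaks within a list. Coordinates are on ce11.

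Nearly all nuclear IDR summits lay inside a region of each replicate's list, mostly in the same order of strength. Of the 1894 nuclear IDR summits, 97.4% lay inside a region of replicate 1's list and 97.9% inside one of replicate 2's list. Regions of both lists held 1807 of them. Each list holds 30000 regions from before the threshold, background included, so lying inside one is not by itself detection as a peak. When each replicate's list was limited to its 1894 strongest nuclear peaks, 70.4% of replicate 1's summits lay inside a peak of replicate 2 (exact 95% interval 68.3 to 72.5%). Over the 1807 IDR peaks matched in both lists, Spearman's rho of the scores was 0.77 (95% bootstrap interval 0.75 to 0.79). This correlation is across peaks, which are not independent replicates. The IDR set was itself derived from the lists of both replicates and the pooled list, so it may favour peaks on which the replicates agree.

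The strongest nuclear peak lay at cux-7, which encodes a protein with an RNA recognition motif. Its summit at position 7520845 of chromosome III (peak 7520695 to 7521003) coincided with the annotated 5' end of cux-7 (WBGene00000854, 7518628 to 7520845, minus strand) and fell in a 5' UTR. Its score was 2614 in the pooled data, 1366 in replicate 1 (rank 1) and 1263 in replicate 2 (rank 2). The same summit was also in the window of C07H6.2, annotated as an E3 ubiquitin-protein ligase, at -164 bp from its 5' end (negative values are upstream). Other protein-coding genes next to the strongest nuclear peaks were C47E8.4 (FAM50 homolog, score 1913), tasp-1 (TASPase homolog, 1801), T07F10.3 (1706), Y56A3A.7 (annotated as a cut-like homeobox protein, 1697), F25H9.7 (succinate dehydrogenase assembly factor, 1691) and rpl-3 (large ribosomal subunit protein uL3, 1668). The tasp-1 summit was at position 10759258 of chromosome III, at -49 bp, and the F25H9.7 summit at 13468378 of chromosome V, in the 5' UTR. The second strongest nuclear peak, at 14055225 of chromosome V with a score of 2369, had no 5' end of a gene within 500 bp of its summit. The third, at 8028472 of chromosome II with a score of 2328, lay beside the non-coding RNA genes C08B11.13 and C08B11.11.

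Of the 20 strongest peaks in the IDR set, 13 were mitochondrial, and the remaining ones were those named from cux-7 to Y56A3A.7, including the 2 without a protein-coding gene as the nearest within 500 bp. The genes of the nuclear peaks ranked below these, from F25H9.7 on, were named after their scores were seen. They included mog-4, a splicing helicase (1613), sco-1 (1537), thoc-5, a subunit of the THO complex (1354), and cdc-48.1, a homolog of the transitional endoplasmic reticulum ATPase (1341).

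LIR-3 peaks were concentrated at the 5' ends of genes. Of the 1894 nuclear summits, 1277 (67.4%, exact 95% interval 65.3 to 69.5%) lay within 500 bp of the annotated 5' end of a gene other than a piRNA gene. Random placements of the same number of summits on the same chromosomes gave 25.9% on average, a 2.61-fold difference (permutation test, one-sided, 1000 placements, p = 0.001, the smallest they can give). Summits were rare in coding exons, with 1.9% against 24.2% of random positions. Of all summits, 72% lay outside protein-coding genes and tRNA, snoRNA, snRNA and rRNA genes, against 37.5% of random positions. Introns of protein-coding genes held 19.1% of the summits and 33.3% of random positions, 5' UTRs held 2.8% and 1.44%, and 3' UTRs held 1.27% and 3.53%. At protein-coding genes with a summit in the window, the strongest one lay upstream of the 5' end in 92.8% of 1216 genes, at a median of -187.5 bp.

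**Figure D1:**
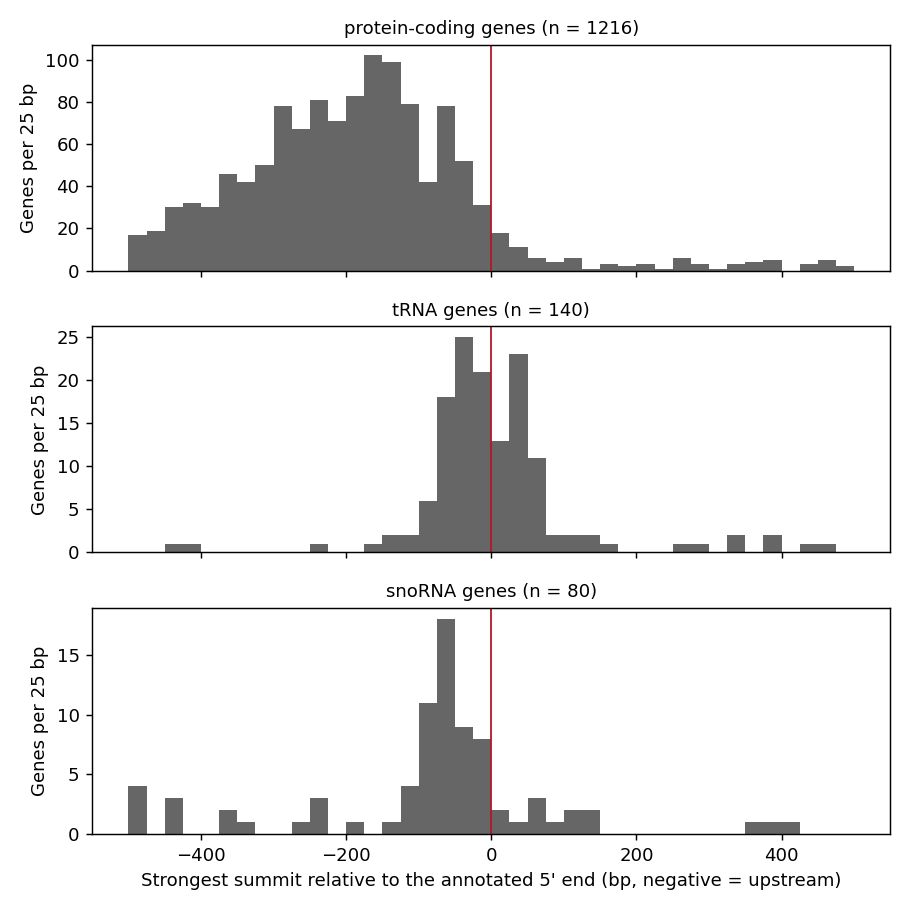
Position of the strongest IDR summit within 500 bp of the annotated 5' end, in bp (x axis, negative is upstream, red line at the 5' end), as the number of genes per 25 bp (y axis), for protein-coding, tRNA and snoRNA genes. The medians are -187.5 bp for 1216 protein-coding genes, -10 bp for 140 tRNA genes and -64.5 bp for 80 snoRNA genes.

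Genes for tRNAs, snoRNAs and snRNAs carried LIR-3 peaks more often than other genes. A summit lay within 500 bp of the 5' end of 140 of 612 nuclear tRNA genes (22.9%, exact 95% interval 19.6 to 26.4%), 5.6-fold the share among all other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 6.47e-60). Among snoRNA genes, whose products guide the modification of other RNAs, the count was 80 of 346 (23.1%, 18.8 to 27.9%, 5.52-fold, exact adjusted p = 5.48e-35). Among snRNA genes it was 16 of 129 (12.4%, exact 95% interval 7.26 to 19.4%, 2.88-fold, adjusted p = 0.000214). With the 15363 piRNA genes left out of the background, an alternative chosen after seeing the data, these 3 biotypes still passed, at 3.92-fold, 3.87-fold and 2.02-fold (exact adjusted p = 7.54e-42, 9.83e-25 and 0.0191). Among the 947 strongest IDR peaks the tRNA gene share was 7.68%, 3.31-fold that of all other genes, and the snoRNA gene share 11% and 4.72-fold (exact adjusted p = 7.63e-12 and 2.83e-14). Over 9 alternatives the exact adjusted p ranged from 1.63e-72 to 7.63e-12 for tRNA and from 2.04e-42 to 2.83e-14 for snoRNA genes. None of these alternatives was limited to tRNA genes in unique sequence. The median share of unique 31-mers within 100 bp was 69% for tRNA genes on X and 68.7% for autosomal ones. Only 11 tRNA genes on X and 27 on autosomes were at least 90% unique, and 2 of each had a peak (18.2% and 7.41%). Whether reads shared between tRNA gene copies add to the tRNA gene share thus stays open.

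For protein-coding and unclassified ncRNA genes the comparison depended on whether piRNA genes were counted among the other genes. Protein-coding genes had a summit in 1216 of 19973 cases (6.09%) against 3.02% of all other genes (exact adjusted p = 3.21e-57), and against 6.31% of the others without piRNA genes (adjusted p = 0.656). Unclassified ncRNA genes had one in 450 of 7764 (5.8%) against 4.04% of all other genes (exact adjusted p = 3.36e-11), and against 6.29% without piRNA genes (adjusted p = 0.219). When each summit was also given only to the gene with the nearest 5' end, the share was 2.82% for ncRNA genes against 4.4% (exact adjusted p = 4.91e-10), and 4.21% for protein-coding genes against 3.67% (adjusted p = 0.0299). Over 9 alternatives the exact adjusted p ranged from 6.06e-74 to 0.656 for protein-coding and from 1.29e-20 to 0.219 for ncRNA genes.

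Summits at tRNA genes lay closer to the annotated 5' end than those at protein-coding genes. Their median offset from the 5' end was -10 bp and 85% of them lay within 100 bp of it, against 19.9% at protein-coding genes, a difference that was not tested. Starts of transcription were not measured here, so the distances of summits from them are not known. The tRNA genes with the strongest peaks were C18A11.t2, a tRNA-Arg gene on X (score 656, summit 8036432, 325 bp downstream of the 5' end), Y38E10A.t1, a tRNA-Ala gene on II (638, summit 12678076, at -238 bp), and the adjoining tRNA-Ala genes F15G9.t1 and F15G9.t2 on X, which share a summit at 9743688 in an intron of a protein-coding gene (629). No tRNA isotype passed the test against the other tRNA genes after adjustment over 21 isotypes (Fisher's exact test, two-sided, every adjusted p = 1). Shares ranged from 10% for tRNA-Met to 30.8% for tRNA-Leu, leaving out the single tRNA-Sec gene, which had a peak. The strongest snoRNA gene peaks were at C06A1.9 (1341, the summit at cdc-48.1, at -494 bp), F59C6.15 (1109), F39B2.14 (738) and F54E7.10 (685). Among snRNA genes the strongest peaks were at the spliced leader genes sls-2.1 (879), sls-2.4 (810.2) and sls-2.2 (653), with summits at -30, -35 and -21 bp, and at R07E5.16 (574).

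Pseudogenes and piRNA genes carried peaks less often than other genes. A summit lay near 14 of 2128 pseudogenes (0.658%, exact adjusted p = 6.86e-25), with the strongest at R12C12.8 (score 1274), pqbp-1.2 (657), F07H5.5 (545, with no matching peak in replicate 1's list) and K08F11.6 (385). It lay near 84 of 15363 piRNA genes (0.547%, exact adjusted p = 2.07e-232), over 42 distinct summits, led by 21ur-11261 (910.1). No call was made for miRNA genes (14 of 261, adjusted p = 0.413), lincRNA genes (11 of 194, adjusted p = 0.413) or rRNA genes (0 of 20, exact upper limit 16.8%, adjusted p = 1). With a 1000 bp window lincRNA genes passed, with more peaks (10.3%, exact adjusted p = 0.0146, range over 9 alternatives 0.0146 to 1).

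**Figure D2:**
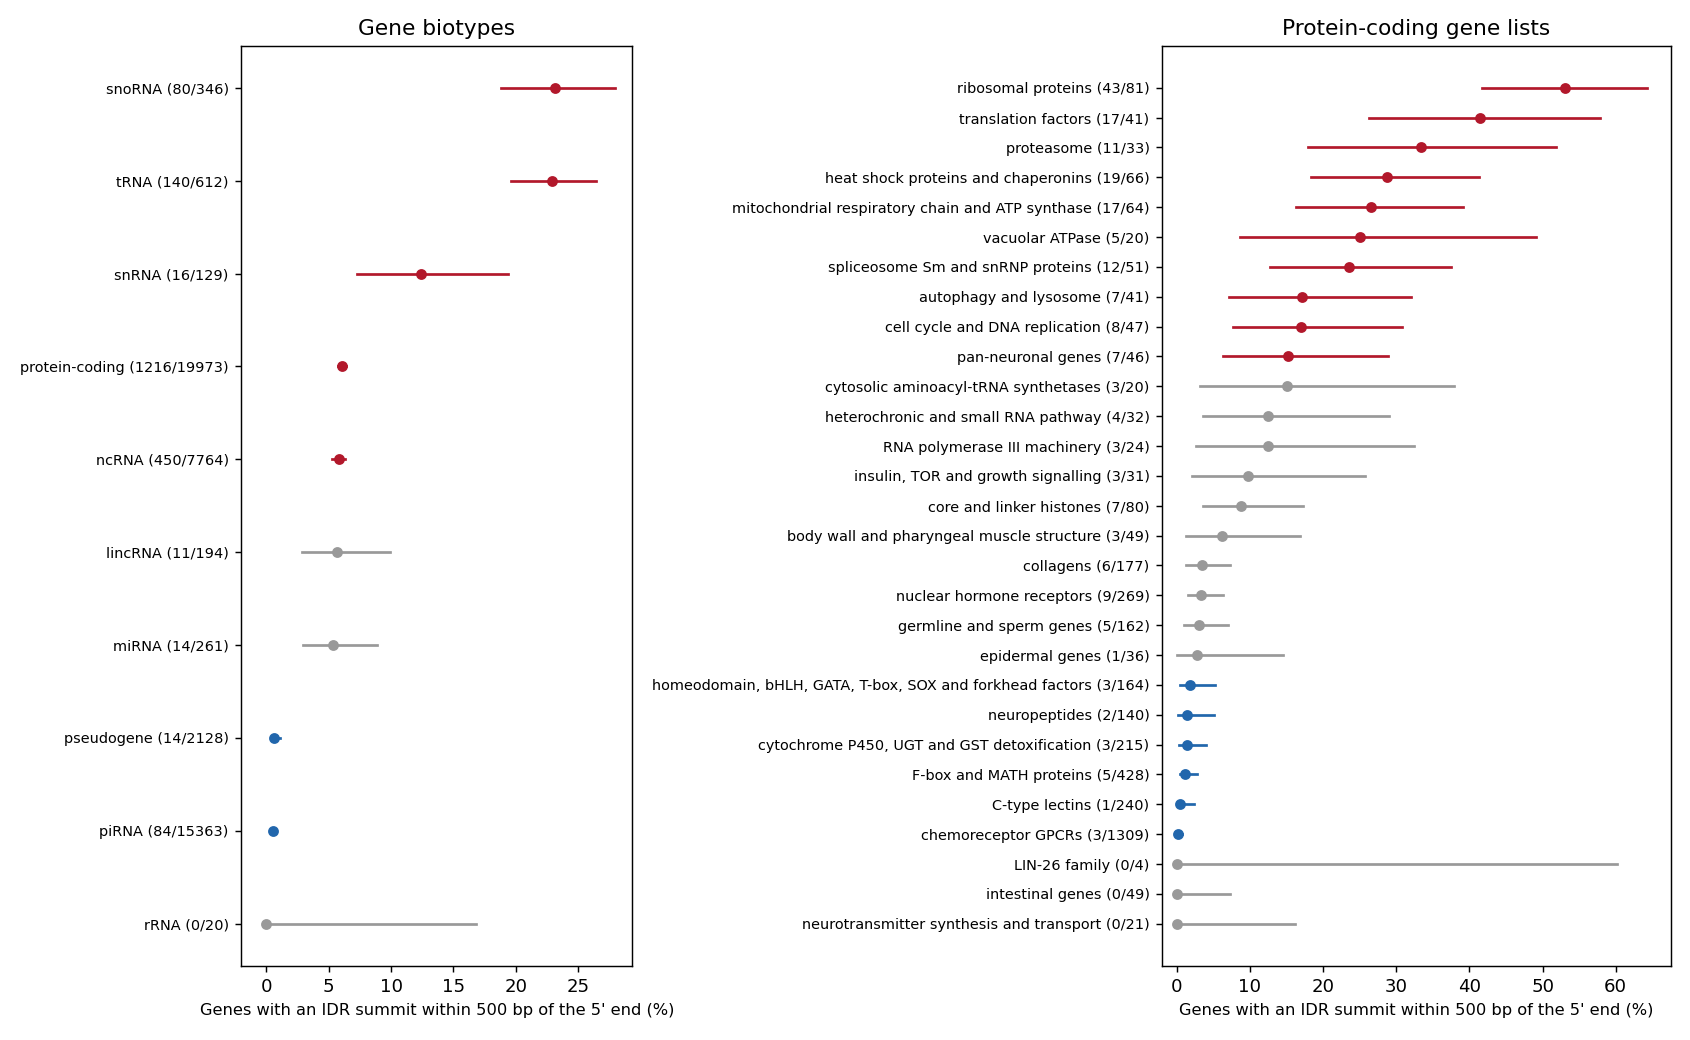
Percentage of genes with an IDR summit within 500 bp of the 5' end (x axis) for each biotype (left, against all other genes with piRNA genes included) and each list of protein-coding genes (right), with the number of genes with a summit and the total. Points are shares and lines exact 95% intervals, in red where the share is above and in blue where it is below that of the other genes with adjusted p under 0.05, and in grey otherwise; ribosomal protein genes reach 53.1% and chemoreceptor genes 0.229%.

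Among the lists of protein-coding genes, ribosomal protein, translation factor, proteasome and chaperone genes had the highest shares with a peak at the 500 bp window. Ribosomal protein genes had a summit in 43 of 81 cases (53.1%, exact 95% interval 41.7 to 64.3%), 9-fold the share of other protein-coding genes (adjusted p = 7.47e-30), at 41 distinct summits. The strongest were rpl-3 (score 1668, summit 3867571 on III, at -283 bp), rpl-35 (1402, 7854693 on III, at -441 bp), rpl-20 (1239) and rpl-15 (1209). These 4 summits lay outside protein-coding and small RNA genes. Translation factor genes had one in 17 of 41 cases (41.5%, exact adjusted p = 7.06e-10), led by eif-3.B (1333), iff-2 (797), eef-1A.1 (598) and eif-3.E (538). Proteasome genes had one in 11 of 33 (33.3%, exact adjusted p = 9.4e-06), with rpn-3 (366), rpn-11 (342), pas-3 (307) and rpn-9 (221) the strongest. Heat shock protein and chaperonin genes had one in 19 of 66 (28.8%, exact adjusted p = 5.65e-08), among them cct-1, T-complex protein 1 subunit alpha (789), the prefoldin genes pfd-5 (752) and pfd-4 (551), and hsp-3, a 70 kDa heat shock protein (536). These shares depended on the window: with 250 bp they were 12.3% for ribosomal protein genes, 26.8% for translation factor genes, 27.3% for proteasome genes and 16.7% for chaperone genes. With each summit given to the nearest gene they were 24.7%, 26.8%, 21.2% and 10.6%. Each of these 4 lists passed under all 9 alternatives, with the highest exact adjusted p 0.00417, 6.62e-06, 0.0031 and 0.04.

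The respiratory chain, spliceosome, vacuolar ATPase, cell cycle, autophagy and pan-neuronal lists also carried peaks more often than other protein-coding genes. Mitochondrial respiratory chain and ATP synthase genes had a summit in 17 of 64 cases (26.6%, and 14.1% with 250 bp or the nearest gene only, exact adjusted p = 1.01e-06, range 8.93e-09 to 0.00533), led by cox-5A (742), atp-5 (666), atp-1 (407) and atp-2 (327). Spliceosome genes had one in 12 of 51 (23.5%, exact adjusted p = 0.000137), with snr-1 (349, with no matching peak in replicate 2's list), snr-4 (262) and the divergent pair rsp-1 and rsp-2, which share a summit (229). Vacuolar ATPase genes had one in 5 of 20 (25%, exact adjusted p = 0.0157), including vha-8 (256.3), vha-12 (182), vha-9 (119.1) and vha-15 (116.5). Cell cycle and DNA replication genes had one in 8 of 47 (17%, exact adjusted p = 0.0168), led by lin-35, a retinoblastoma-like protein homolog (842), pole-1 (503), cul-4 (408) and cdc-6 (290.2). Autophagy and lysosome genes had one in 7 of 41 (17.1%, exact adjusted p = 0.0248), led by lgg-2 (564), epg-7 (327), epg-8 (280.5) and epg-6 (144). Pan-neuronal genes had one in 7 of 46 (15.2%, exact adjusted p = 0.0368), led by unc-76 (344), unc-16 (309.9), tag-65 (215) and unc-14 (188). The vacuolar ATPase, autophagy and pan-neuronal calls were lost among the 947 strongest IDR peaks (exact adjusted p = 0.272, 0.296 and 0.0655) and against genes near a pooled pre-threshold summit (adjusted p = 0.105, 0.244 and 0.127). Among the 947 strongest peaks their odds ratios were 2.89, 2.05 and 3.18, against 5.16, 3.19 and 2.78 at the main settings. The autophagy call was also lost without replicate 2 (exact adjusted p = 0.073), and the spliceosome, vacuolar ATPase and autophagy calls with a 250 bp window (adjusted p = 0.0856, 0.277 and 0.308). Over 9 alternatives the exact adjusted p ranged from 3.04e-07 to 0.0856 for the spliceosome, 0.000631 to 0.277 for the vacuolar ATPase, 0.00533 to 0.308 for autophagy and 0.00508 to 0.127 for the pan-neuronal list.

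Chemoreceptor, F-box and other large gene families carried few peaks. Chemoreceptor genes had a summit in 3 of 1309 cases (0.229%, exact adjusted p = 9.27e-31), at srh-2 (231), srh-16 (226) and srd-44 (153), the last inside a tRNA, snoRNA, snRNA or rRNA gene. F-box and MATH protein genes had one in 5 of 428 (1.17%, exact adjusted p = 2.79e-06), with fbxb-85 (513), sdz-1 (261), fbxb-72 (151) and fbxc-19 (131) the strongest. C-type lectin genes had one in 1 of 240 (0.417%, exact adjusted p = 2.94e-05), clec-126 (133), and in 0 of 240 without replicate 1. Detoxification genes had one in 3 of 215 (1.4%, exact adjusted p = 0.004), namely dhs-1 (539), gst-27 (456) and ugt-2 (95.1635). Neuropeptide genes had one in 2 of 140 (1.43%, exact adjusted p = 0.0261), nlp-4 (167) and flp-23 (103.7). Homeodomain, bHLH, GATA, T-box, SOX and forkhead factor genes had one in 3 of 164 (1.83%, exact adjusted p = 0.0368), hlh-11 (542), ceh-38 (433) and ceh-39 (101.02). The neuropeptide and transcription factor calls were lost under 4 of 9 alternatives each (exact adjusted p over all 9 from 0.0116 to 0.151 and from 0.00383 to 0.187), and the detoxification call among the 947 strongest IDR peaks (exact adjusted p = 0.0655, range 6.72e-05 to 0.0655). Detoxification genes had a summit in 2.33% of cases without replicate 1 and 0.93% without replicate 2 (exact adjusted p = 0.0338 and 0.000535).

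Beyond the pan-neuronal and neuropeptide lists, which passed in opposite directions, marker lists for the tissues of the larva did not differ detectably from other protein-coding genes. A summit lay near 3 of 49 muscle structure genes (6.12%, adjusted p = 1; 2.04% without replicate 1 and without replicate 2, adjusted p = 0.444 and 0.449, range 0.348 to 1), 1 of 36 epidermal genes (adjusted p = 0.777), 0 of 49 intestinal genes (exact upper limit 7.25%, adjusted p = 0.119) and 0 of 21 neurotransmitter synthesis and transport genes (upper limit 16.11%, adjusted p = 0.709). It lay near 5 of 162 germline and sperm genes (exact adjusted p = 0.186) and 6 of 177 collagen genes (adjusted p = 0.204). No call was made at the main settings for nuclear hormone receptors (9 of 269, exact adjusted p = 0.119), histones (7 of 80, adjusted p = 0.412), cytosolic aminoacyl-tRNA synthetases (3 of 20, adjusted p = 0.181), the RNA polymerase III machinery (3 of 24, adjusted p = 0.223), insulin, TOR and growth signalling (3 of 31, adjusted p = 0.504) or the heterochronic and small RNA pathway (4 of 32, adjusted p = 0.185). For the RNA polymerase III machinery the count was 1 of 24 without replicate 1 and 3 of 24 without replicate 2. Collagens passed the test, with fewer peaks, when a 250 bp window was used (0% of genes, exact adjusted p = 0.00459, range over 9 alternatives 0.00459 to 0.8), and with the nearest gene only (0.565%, adjusted p = 0.02). The heterochronic and small RNA pathway passed it, with more peaks, at 1000 bp (31.2%, exact adjusted p = 0.000332, range 0.000332 to 0.526). Germline and sperm genes passed, with fewer peaks, without replicate 1 (1.85%, exact adjusted p = 0.0338, range 0.0338 to 1). Nuclear hormone receptors passed, with fewer peaks, against genes near a pooled pre-threshold summit (8.65%, exact adjusted p = 0.0455, range 0.0455 to 0.348).

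Peaks at chaperone and ribosomal protein genes were among the stronger ones, and peaks at tRNA genes among the weaker ones. On a scale from 0 (weakest) to 100 (strongest) within the IDR set, the 19 peaks at heat shock protein and chaperonin genes had a mean percentile of 74.4 against 49.8 for the other peaks (permutation test with 100000 resamples, two-sided, adjusted p = 0.00065). The 42 peaks at ribosomal protein genes averaged 70.35 against 49.6 (permutation adjusted p = 7.5e-05) and the 952 at protein-coding genes 55.9 against 44.1 (adjusted p = 7.5e-05), both with the smallest unadjusted p the resamples can give. The 125 peaks at tRNA genes averaged 41.6 against 50.6 (permutation adjusted p = 0.00225). The median share of unique sequence around tRNA genes was 69% on X and 68.7% on autosomes. Whether reads shared between tRNA gene copies change the scores of these peaks was not tested. The other 11 of 15 classes tested, snoRNA genes among them (51.2 against 50, permutation adjusted p = 0.831), did not pass. Among the 947 strongest peaks the chaperone difference no longer passed (permutation adjusted p = 0.269, range over 3 alternatives 0.0009 to 0.269). Translation factor peaks (66.3 against 49.9, permutation adjusted p = 0.0562) passed without replicate 1 (adjusted p = 0.0487, range 0.0487 to 0.526). Peaks at piRNA genes (41 against 50.2, permutation adjusted p = 0.0967) passed without replicate 2 (adjusted p = 0.0366, range 0.0366 to 0.3).

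Protein-coding genes on the X chromosome carried peaks less often than autosomal ones. A summit lay near 114 of 2731 X-linked genes (4.17%) and 1102 of 17242 autosomal genes (6.39%; odds ratio 0.638, Fisher's exact test, two-sided, p = 3.11e-06). Gene classes were not matched between X and autosomes. By chromosome the share was highest on III (9.24%) and I (8.58%), and lowest on V (4.06%) and X. The share of all summits on X was 18% (exact 95% interval 16.3 to 19.8%), against 17.7% of the nuclear genome length. Chromosome V held 14.7% of the summits and 20.9% of the length, and III held 17.8% and 13.7%.

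Summit windows held GA repeats more often, and AT-rich motifs less often, than their flanks. GAGAGA, on either strand, was present within 100 bp of 769 of 1894 summits (40.6%, exact 95% interval 38.4 to 42.9%) and in 10.3% of 3746 flanking windows centred 500 bp away (odds ratio 5.93, Fisher's exact test, two-sided, adjusted p = 2.58e-147). The E box CACGTG was present in 10.1% and 3.71% (exact adjusted p = 2.74e-20), the Sp1-like box CCGCCC in 8.98% and 3.28% (adjusted p = 4.7e-18), and the cyclic AMP response element TGACGTCA in 1.8% and 0.801% (adjusted p = 0.00128). Matches to the internal B box of tRNA genes were present in 8.61% and 4.32% (exact adjusted p = 3.54e-10), a difference that was gone without the summits within 500 bp of a tRNA gene (odds ratio 0.988, adjusted p = 1, range over 4 alternatives 1.37e-10 to 1). The GATA site TGATAA was less frequent at summits (13.1% against 18.7%, exact adjusted p = 1.13e-07), as were TATAAA (16.8% against 20.8%, adjusted p = 0.00037) and runs of T (10.9% against 19%, adjusted p = 2.85e-15). The flanks were not matched to summits in distance from gene 5' ends, near which 67.4% of summits lay. These comparisons therefore do not separate what is particular to summits from what is common to promoters.

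The short sequences at summits changed with peak strength, as seen with 8-mers and a division at rank 400 chosen after the peaks were examined. From the windows of 50 bp on each side of summits on chromosomes I, III and V, 10 8-mers were taken from peaks ranked up to 400 and 10 from the other peaks, and both sets were then counted on II, IV and X. The set from the strongest peaks, which includes CTAGGCCA and GGAGTACA, was present in 43.8% of the 48 windows ranked up to 100 there (exact 95% interval 29.5 to 58.8%), in 17.4% of the next 46, ranked up to 200, in 16.13% of the next 93, ranked up to 400, and in 5.52% of the 145 weakest (2.41 to 10.6%). The other set, which includes AGACGCAG and GAGAGAGA, was present in 16.7% (7.48 to 30.2%), 26.1%, 37.6% and 35.2% (27.4 to 43.5%) of the same windows, with its highest share, 42%, at ranks above 800 and up to 1200. The set from the strongest peaks was thus the more frequent one at ranks up to 100 and the less frequent one in every later range of ranks, and the difference between the sets was not tested.

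**Figure D3:**
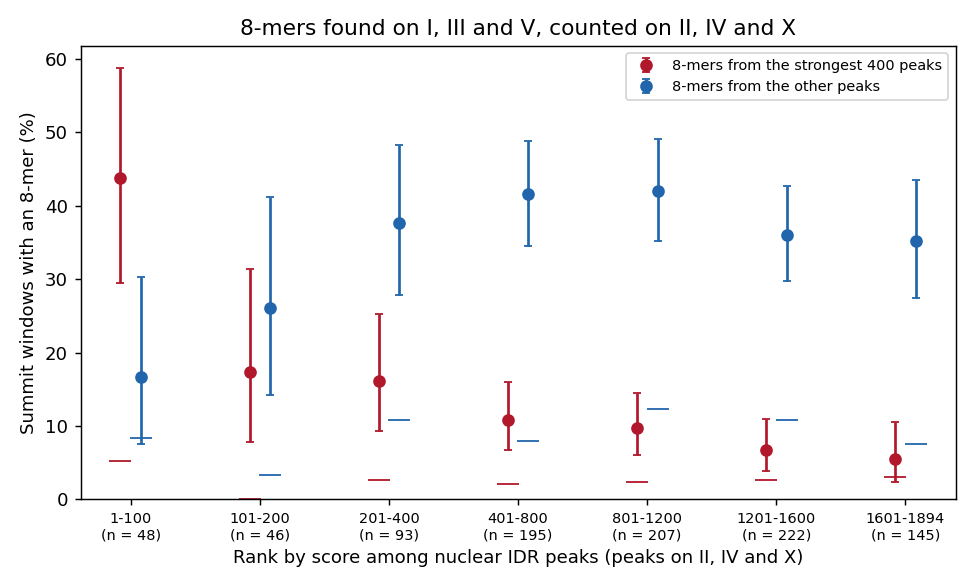
Percentage of summit windows on II, IV and X with any 8-mer of a set (y axis) by rank of the peak's score (x axis, with the number of peaks), for the set from the strongest 400 peaks (red) and the set from the other peaks (blue), with exact 95% intervals as bars and flanking windows as dashes. The red set falls from 43.8% to 5.52% and lies above the blue set only among the strongest 100, where the blue set is at 16.7%.

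No IDR summit lay within 20000 bp of lir-3 itself (WBGene00003046, chromosome II, 11183075 to 11184807, minus strand), the gene carried by the transgene. Replicate 1's own list had 0 summits in that region and replicate 2's had 4, the strongest at rank 9947. The labels name unc-119 as mutated in the strain. An IDR peak lay in an intron of that gene (WBGene00006843, chromosome III, 10902641 to 10908935) with its summit at 10903223, 582 bp downstream of the 5' end. Its score was 100.1 (rank 1639 of the nuclear IDR peaks, rank 1771 in replicate 1 and 1795 in replicate 2 for the strongest summit near the gene). The tests were planned taking unc-119, like lir-3, to be carried by the transgene. Extra copies could raise signal at such a gene, which was not tested. None of the 4 genes of the lin-26 family (lin-26, lir-1, lir-2 and lir-3) had an IDR summit within 500 bp of the 5' end (exact upper limit 60.2%, adjusted p = 1). The 1 IDR peak within 20000 bp of lir-2, lir-1 and lin-26, which neighbour each other on chromosome II, had its summit at 7662548 and a score of 95.3, outside protein-coding and small RNA genes.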

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

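The mitochondrial genome, which the comparisons above leave out, held 16 IDR peaks, a signal in data outside the main measurement, and the highest score among them, 17386, had its summit 785 bp from the nearest annotated 5' end, that of ND5. All 16 mitochondrial regions in the pooled list were in the IDR set, against 6.32% of the pooled nuclear regions. The next scores were 11264 near tRNA-His and 10898 near CYTB, and no explanation was tested.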

How the results depend on the processing

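The alternatives with the mitochondrial peaks and without piRNA genes in the background were chosen after seeing the data. The first gave 70.7% for the overlap of the replicates' strongest peaks. For the main value or count of each comparison, 57 of 65 values under an alternative kept their direction and side of the threshold, or stayed within the interval or within 1.5 times the count. With reciprocal overlap of at least 50%, the share of replicate 1's strongest peaks found in replicate 2 was 64.5%, the share of IDR summits in both replicates 89.3% and rho 0.739, and the cause was not tested. With the 500 strongest peaks the first of these was 78.6%, and the cause was not tested. Among the 947 strongest IDR peaks, 3 lists passed with fewer peaks in place of 6, and the cause was not tested. Of the lists lost, neuropeptide genes had an odds ratio of 0.186 there and 0.222 at the main settings. Those of detoxification genes were 0.242 and 0.216, and those of the transcription factor list 0.319 and 0.286. The lost calls need not mean smaller differences. Replicate 2's own list, from before the threshold, had 4 summits within 20000 bp of lir-3, against 0 in the IDR set. The strongest was at rank 9947 in that list of 30000 regions. The IDR set holds 1894 nuclear peaks, so these counts were taken at unlike thresholds. For single classes, 389 values kept their call, 20 lost and 8 gained it. Without piRNA genes in the background, 3 biotypes passed with more peaks in place of 5 and 1 with fewer in place of 2, and protein-coding (6.09%) and ncRNA genes (5.8%) turned to below the others without passing, by construction of the comparison group. The other values that turned round were ncRNA genes with nearest-gene assignment (2.82%), a setting that leaves out piRNA genes too, and the tRNA gene B box without summits near tRNA genes (odds ratio 0.988), a setting that takes out the tRNA genes themselves. Without replicate 1 and without replicate 2, 67.6% and 66.7% of summits lay near 5' ends, 10 and 9 lists passed with more peaks and 7 and 6 with fewer, and 5 biotypes with more and 2 with fewer in each. In each, 5 classes differed in strength and 8 motifs passed, and the odds ratio for X was 0.705 and 0.603. No paired analysis was possible because there was 1 group. Read depth, which is not known, limits what can be said of genes without a peak.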

Other observations

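Tests in this part chosen after the results were seen are those of spliced leader RNA genes, of the 8-mers on chromosomes II, IV and X, of the windows of copies with a peak, of promoter position, of muscle genes, of tRNA genes on X against autosomes with its permutation within like unique shares and its comparison with summits away from genes, and the use there of the planned comparison of protein-coding genes. The division at rank 400 was also chosen after the peaks were examined. The design has 1 group, so no explanation that needs a comparison of groups was tested.

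Of the spliced leader RNA genes, 5 of 18 sls-2 genes and 0 of 12 sls-1 genes (exact upper limit 26.5%) had an IDR summit within 500 bp of the 5' end. A difference was not detectable (Fisher's exact test, two-sided, p = 0.0657), and the split was chosen after the values were seen.

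Peaks ranked up to 100 carried the 8-mers taken from the strongest 400 more often than the other set, and lower ranks up to 400 did not. Of the 8-mers taken from summit windows on I, III and V, all 20 were more frequent on II, IV and X at summits than in flanks (Fisher's exact test, one-sided, adjusted p under 0.05), which goes against a chance choice. Many of them are overlapping pieces of the same sequence, as AGGAGTAC and GGAGTACA are, so they do not count as 20 separate sequences. CTAGGCCA was in 9.09% of the strongest summit windows there and 0.802% of flanks, GGAGTACA in 9.09% and 0.535%, while AGACGCAG was in 8.45% and 0.52% of the windows and flanks of the other peaks. On II, IV and X, protein-coding genes with GAGGAGTACA within 500 bp of the 5' end had a peak in 19 of 57 cases (33.3%) and other genes in 5.35% (odds ratio 8.85, Fisher's exact test, two-sided, p = 8.03e-11). Position at any annotated 5' end may thus not account for the pattern, but the test cannot separate sequence from gene class. The other genes include families with few peaks, such as chemoreceptors (0.229% over all chromosomes). Genes of 8 growth lists on II, IV and X with none of the 8-mers had a peak in 35% of cases. Position still mattered for the same sequence: 45 of 170 copies within 500 bp of a gene 5' end had a peak (26.5%) and 14 of 389 farther copies (3.6%). The 59 of 559 copies of GAGGAGTACA with a peak all lay in windows at least 90% unique in 31-mers (100%, exact 95% interval from 93.9%), where few reads can be shared, which argues against reads shared between copies as the source for reads of about that length or more. Read length is not known here, and 485 of all the copies lay in such windows. The test planned for this, of the median unique share, left it open, since the median was 100% with and without a peak (permutation test of ranks, one-sided, p = 0.00012). What reads or protein the sequence brings stays open.

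It stays open whether peaks at growth genes mark open promoters of broadly used genes or a particular sequence. Among 154 genes of 8 growth lists on II, IV and X, 33 of 94 with any of the 8-mers found on I, III and V within 500 bp of the 5' end (35.1%) and 21 of 60 without (35%) had a peak, an odds ratio of 1.005 (exact 95% interval 0.484 to 2.11, Fisher's exact test, two-sided, p = 1). The open promoter explanation needs no difference, but this test cannot decide. Even flanking windows of 50 bp on each side held an 8-mer of the other set in 12.3% of cases at ranks above 800 and up to 1200. Many of the wider windows can thus hold one away from any summit. The interval also leaves room for a part of the sequence, and openness of promoters was not measured. Whether abundant transcription is enough stays open: muscle structure genes had a peak in 6.12% of cases, below the ribosomal protein interval from 41.7%, and in 2.04% without replicate 1 and without replicate 2, but transcript levels were not measured here.

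Nuclear tRNA genes on X carried peaks more often than autosomal ones, opposite to protein-coding genes. The counts were 82 of 276 (29.7%) and 58 of 336 (17.3%; odds ratio 2.03, Fisher's exact test, two-sided, p = 0.00033). Counting clusters of tRNA genes once left an odds ratio of 2.21 (Fisher's exact test, two-sided, p = 0.000163). Clusters on X held more genes each, with 276 genes in 218 clusters against 336 in 306. With each summit given only to the nearest gene, the shares were 22.1% and 14% (odds ratio 1.74, Fisher's exact test, two-sided, p = 0.0104). Both go against shared summits as the whole source of the difference. Protein-coding genes on X had an odds ratio of 0.638, so a higher share on X was not seen at genes of every kind. Gene classes, which differ widely in their share with a peak, were not matched between X and autosomes. The comparison therefore cannot exclude a higher background on X. A higher background on X away from genes stays open: summits farther than 500 bp from the 5' end of any gene but piRNA genes were 1.26 times as frequent per base on X as on autosomes (exact 95% interval 1.03 to 1.53), against a ratio of 1.72 for the tRNA gene shares (95% interval 1.28 to 2.31). Permuting peaks among tRNA genes of like unique 31-mer share gave 63.3 X genes with a peak on average against 82 (permutation test, one-sided, p = 0.0006), which goes against a different share of unique sequence on X. Reads shared between tRNA gene copies stay open, since only 11 and 27 genes were at least 90% unique (odds ratio 2.78, p = 0.564) and the chance of detecting the observed difference with so few was 13.6%.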
